A study of Caenorhabditis elegans with 4 samples.

How the data were processed

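The study mapped the genomic binding sites of NFYA-1 in Caenorhabditis elegans by chromatin immunoprecipitation followed by sequencing (ChIP-seq). NFYA-1 is the A subunit of NF-Y, a heterotrimeric transcription factor that recognises CCAAT boxes. The worms carried a transgene that encodes NFYA-1 fused to green fluorescent protein (GFP), and the chromatin was precipitated with an antibody against GFP. Per the labels' protocols, hermaphrodites at the L3 larval stage, grown at 20 °C, were fixed with 2% formaldehyde, sonicated and immunoprecipitated, and 10% of each extract was kept as input DNA. The series holds 4 samples, made up of 2 ChIP samples and 2 input samples. The ChIP samples are numbered replicate 1 and replicate 2 in their titles. The labels do not say whether the replicates came from separate cultures, so the agreement between them may include agreement of a technical kind.

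The authors deposited 3 peak lists, which are one list for each ChIP replicate and one that they called combined. Per the file headers, coordinates are on the WormBase WS180 genome build, and the lists name PeakSeq as the peak caller. PeakSeq scores regions of ChIP reads against a control library. Each peak has a start, an end and a q value, which the deposited lists repeat in the attribute column and which is the authors' own value. The aligner, the PeakSeq version, the read filters, the control used for each list and the way in which the replicates were combined are not given in the sources used here. The lists hold no read counts, fold enrichments or summits, so the sequencing depth behind each peak is unknown, and no interval or detection limit could be based on reads. The input samples had 0 peak lists of their own here and entered no comparison.

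Peak strength was expressed as −log10 of the authors' q value. Strength was ranked within a list, where rank 1 is the smallest q value. Positions are 1-based. Peaks were taken as overlapping when they shared at least 1 bp (bedtools 2.31.1), and the overlap of the replicate lists was compared with 10000 circular shifts of one list along each chromosome (one-sided). The smallest p-value these shifts allow is 0.0001. Shares of peaks carry exact 95% binomial intervals (Clopper-Pearson) and densities carry exact 95% Poisson intervals. Both treat peaks as independent and cover counting error only. Correlations between replicates were computed across peaks matched one to one, with 100000 permutations, and peaks are not independent replicates. Differences in median rank or width used 100000 permutations (two-sided), for which the smallest p-value is 1e-05. Chromosome counts were compared with chromosome length by a chi-square statistic with 100000 multinomial draws and by exact binomial tests.

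WS180 chromosome lengths were not used here. The largest peak coordinate on each chromosome in any of the 3 lists served in their place, which makes each density a slight overestimate. Because neighbouring peaks are not independent, each chromosome was also compared with the others by permuting 1 Mb bins. The central 50% of a chromosome was taken between 25% from each end of that length, and the share of peaks in it was tested against 10000 circular shifts. The spacing of peaks was compared with 1000 random placements of every peak within its own 200 kb bin. Several comparisons were added after the data were seen. These are the ones of the central 50%, of single chromosomes other than X, of 1 Mb bins, of X peak strength and width, of recovery by strength, of strength with width, of which replicate was stronger, and of spacing. The comparison of X with autosomes in the share of combined peaks absent from both replicates was also unplanned. Some alternative settings of the replicate overlap and of the chromosome comparisons were also added then, among them the replicate 1 list shortened to the length of the replicate 2 list, and the closing section names them. The other comparisons in the results and their tests were fixed before the data were examined.

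The plan also held a test of promoter location, 3 tests of the CCAAT motif and tests of gene lists. These need a genome sequence or gene annotation of WS180, which was not used here. A gene table of another assembly, WBcel235, was at hand. Its coordinates were not joined to peaks of WS180, because positions differ between assemblies, so no peak is assigned to a gene. Peaks are named by position instead. The rule, fixed beforehand, names the 25 combined peaks with the smallest q values among those that overlap a peak of both replicates. The scripts were tested on simulated lists. In the simulated replicate overlap, with 2952 peaks, a planted share of 69.0% was recovered as 69.1%. The planted peaks were exact copies, so this checks the counting only. Of 100 pairs of independent lists, which were shorter and tested with fewer shifts than the real lists, 7 passed the 0.05 threshold. The analysis used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.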

Results

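NFYA-1::GFP occupancy in L3 larvae was deposited as 3 PeakSeq peak lists, one for each of 2 ChIP replicates and one combined. The replicate 1 list held 3037 peaks that covered 1.91 Mb, and the replicate 2 list held 2188 peaks that covered 1.35 Mb. The combined list was 1.40 times as long as that of replicate 1, with 4256 peaks over 2.80 Mb. Most peaks were narrow. The median width was 438 bp in replicate 1 (interquartile range 349 to 657 bp), 437.5 bp in replicate 2 (349 to 651 bp) and 451 bp in the combined list (356 to 679 bp). Peaks of 2000 bp or wider made up 3.23%, 2.88% and 3.67% of these lists. The weakest peak retained had a q value of 0.000208 in replicate 1, 0.000170 in replicate 2 and 0.000258 in the combined list. Peaks with smaller q values tended to be wider. The lists hold no read counts or enrichments, so a dependence of the q value on region width cannot be told apart from stronger binding. Across peaks, Spearman's rho between strength and width was 0.37 in replicate 1, 0.36 in replicate 2 and 0.38 in the combined list (permutation p = 1e-05 for each, the smallest that 100000 permutations can give).

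The strongest NFYA-1 regions were found on all 6 chromosomes and were recovered in both replicates. The top-ranked region lay on chromosome II from 5659961 to 5664007 (WS180), with a q value of 4.99e-308 in the combined list, and it ranked 1 in replicate 1 (q = 3.54e-224) and 1 in replicate 2 (q = 2.36e-228). The region on chromosome IV from 8430698 to 8433483 ranked 2 in all 3 lists, with a combined q value of 7.97e-278. On the X chromosome, the strongest region spanned 16929155 to 16932120 (combined rank 3, q = 1.08e-251) and ranked 7 in replicate 1 and 15 in replicate 2. It was followed on X by 4142080 to 4148478, 6090647 to 6093577, 6735431 to 6745995 and 4523319 to 4526709. Chromosome III carried 4 of the 25 named regions, of which 11828841 to 11829929 was the strongest (combined rank 7, q = 3.33e-199). Chromosome V held 4, led by 19519398 to 19523587 (combined rank 9, q = 9.55e-181), and chromosome I held 3, led by 5372066 to 5381667 (combined rank 6, q = 1.60e-202).

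The named regions were distributed as 3 on I, 5 on II, 4 on III, 4 on IV, 4 on V and 5 on X. They were wider than the typical peak, with a median width of 3116 bp and a range of 527 to 11151 bp, and 19 of the 25 reached 2000 bp. Of the 25 regions, 21 held a peak ranked within the top 50 of both replicate lists. The exceptions were broad regions whose replicate peaks were split or weaker. The widest, on chromosome II from 10541812 to 10552962 (11151 bp), ranked 14 in the combined list and 28 in replicate 1, but its best peak in replicate 2 ranked 220. The region on X from 6735431 to 6745995 (10565 bp) was called as 2 peaks in replicate 1 and as 1 peak of 9675 bp in replicate 2. Several strong regions were compact in every list. The region on III from 8528763 to 8529289 measured 527 bp in the combined list, 515 bp in replicate 1 and 506 bp in replicate 2, with a combined q value of 2.06e-145. The region on IV from 15570554 to 15571305 measured 752 bp (combined q = 2.44e-185) and ranked 8 in replicate 1 and 4 in replicate 2. The genes at these positions were not analysed here.

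The replicate lists were next compared to ask how many sites were found in both ChIP samples. Nearly every replicate 2 peak was also a replicate 1 peak. Of the 2188 replicate 2 peaks, 2078 (94.97%, 95% interval 94.0 to 95.9%) overlapped a replicate 1 peak, against a mean of 3.98% when one list was shifted along the chromosomes (circular-shift permutation p = 0.0001). In the other direction, 2070 of 3037 replicate 1 peaks (68.2%, 66.5 to 69.8%) overlapped a replicate 2 peak, against 2.87% after shifting (permutation p = 0.0001, the smallest that 10000 shifts can give). With the replicate 1 list shortened to its 2188 strongest peaks, the overlap was 84.0% of replicate 1 and 84.4% of replicate 2.

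Recovery depended on peak strength. All 608 peaks in the strongest 20% of replicate 1 were found in replicate 2. The share was 96.4% (585 of 607) in the next 20%, then 76.0%, 45.6% and 22.7% in the weakest 20%. In replicate 2, all 438 peaks of the strongest 20% and 82.4% of the weakest 20% were found in replicate 1. Replicate 1 peaks that were not found in replicate 2 had a median −log10 q of 4.90, against 11.8 for those that were. The difference in median rank was 44.96 percentage points of the list (permutation p = 1e-05). In replicate 2 the corresponding medians were 4.42 and 8.55, and the ranks differed by 39.5 percentage points (permutation p = 1e-05). The strongest peak found in replicate 1 alone lay on chromosome IV from 16415094 to 16415904 (q = 3.01e-18, rank 634). The strongest found in replicate 2 alone lay on chromosome III from 4561981 to 4562512 (q = 2.82e-08, rank 1169).

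**Figure D1:**
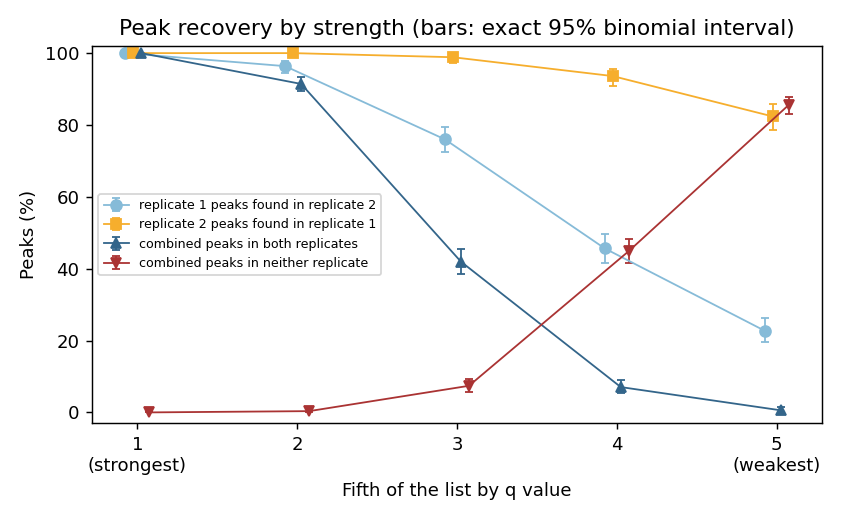
Share of peaks recovered (y axis, percent) by step of 20% of each list, from strongest to weakest q value (x axis), for replicate 1 peaks in replicate 2, replicate 2 peaks in replicate 1, and combined peaks in both or neither replicate, with exact 95% binomial intervals. Recovery of replicate 1 peaks falls from 100% to 22.7%, and combined peaks seen in neither replicate rise from 0 of 852 to 85.5%.

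Peaks found in both replicates kept a similar order of strength. Over 2036 peaks matched one to one, Spearman's rho between the replicates' −log10 q values was 0.85 and Pearson's r was 0.97 (permutation p = 1e-05 for each). Without the 2 peaks farthest from the median, r was 0.96. Matched peaks were usually stronger in replicate 1, in 1669 of 2036 cases (82.0%, 80.2 to 83.6%; exact binomial p = 1.08e-197). The median −log10 q was 11.8 in replicate 1 and 8.45 in replicate 2. These p-values are across peaks of 2 samples and do not measure variation between further replicates.

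**Figure D2:**
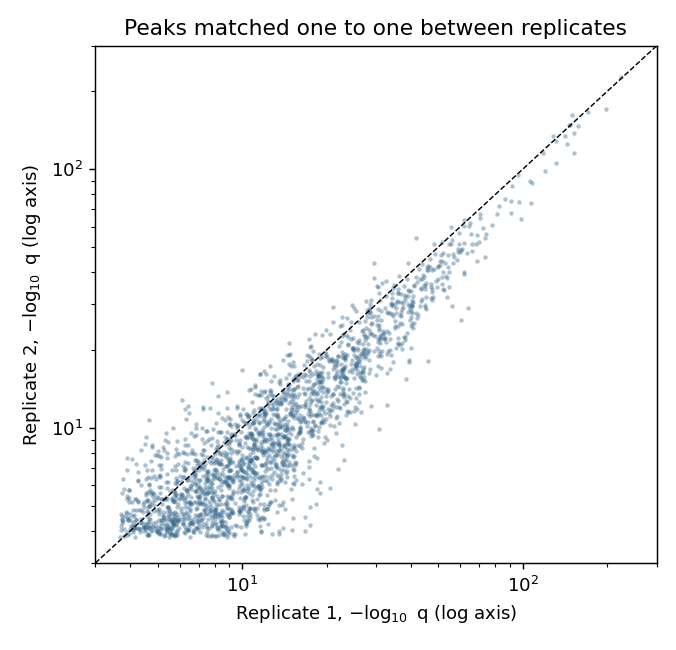
Strength of the 2036 peaks matched one to one between replicates, as −log10 of the authors' q value in replicate 1 (x axis) and replicate 2 (y axis), both on log axes, 1 point per peak, with the dashed line marking equal values. Most points (82.0%) lie below the line, where replicate 1 is the stronger.

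The combined list held nearly all replicate peaks and a further set of weak ones. It overlapped 3003 of 3037 replicate 1 peaks (98.9%, 98.4 to 99.2%) and 2184 of 2188 replicate 2 peaks (99.8%, 99.5 to 99.95%). Of its 4256 peaks, 2052 (48.2%, 46.7 to 49.7%) overlapped a peak of both replicates, 925 (21.7%) of replicate 1 alone and 103 (2.42%) of replicate 2 alone. The remaining 1176 (27.6%, 26.3 to 29.0%) overlapped neither. Peaks in both replicates had a median −log10 q of 19.9 and a median width of 524 bp. Those in neither had 4.75 and 405 bp. All 852 peaks in the strongest 20% of the combined list overlapped both replicates. Among these, 0 of 852 overlapped neither, which allows a share of up to 0.352% when 3 peaks are taken as the limit of a count of 0 (Clopper-Pearson upper limit 0.432%), whereas 728 of 851 (85.5%, 83.0 to 87.8%) in the weakest 20% did. The strongest combined peak without a replicate peak lay on chromosome I from 1069106 to 1070410 (q = 1.23e-13, rank 1605). The share in both replicates was 87.7% among the stronger 50% of the combined list.

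The distribution over chromosomes was then examined. NFYA-1 peaks were densest on chromosome III, with 66.8 peaks per Mb (95% interval 62.6 to 71.3) in the combined list, and sparsest on V, with 30.3 (28.0 to 32.8), and X, with 32.3 (29.7 to 35.1). Chromosomes I, IV and II had 48.8, 45.2 and 39.8 peaks per Mb. The counts departed from chromosome length (chi-square 327, Monte Carlo p = 1e-05). Chromosome III had 1.66 times the density of the other autosomes (1.54 to 1.79), and X had 0.723 times the density of the autosomes (0.661 to 0.790; exact binomial p = 7.73e-14). When 1 Mb bins were permuted in place of single peaks, chromosome III remained denser than the rest (adjusted p = 6e-05 over 6 chromosomes, permutation test), and V (adjusted p = 0.00114) and X (adjusted p = 0.0157) remained sparser. Chromosome I, higher than the rest by the exact binomial test (1.18 times, adjusted p = 0.000109), did not pass when bins were permuted (adjusted p = 0.211).

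In both replicates chromosome III was the densest, with 50.9 peaks per Mb in replicate 1 and 37.8 in replicate 2. X had 20.0 and 13.9 peaks per Mb, and V had 22.3 and 15.98, so that X was the sparsest in each replicate and V in the combined list. The ratio of X to autosomal density was 0.613 in replicate 1 and 0.592 in replicate 2, and 0.544 for the stronger 50% of combined peaks. X peaks were wider than autosomal peaks in the combined list (median 546 against 438 bp), in replicate 1 (549 against 427 bp) and in replicate 2 (586.5 against 419 bp), each with permutation p = 1e-05. They ranked as weaker in the combined list, with a median rank at 61.6% of the list against 48.4% (permutation p = 1e-05), and in replicate 1, at 56.3% against 49.3% (permutation p = 0.0122). In replicate 2 the medians were 52.1% and 49.9% (permutation p = 0.519). Among combined peaks found in both replicates, the median −log10 q was 18.6 on X and 20.2 on autosomes (permutation p = 0.167).

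**Figure D3:**
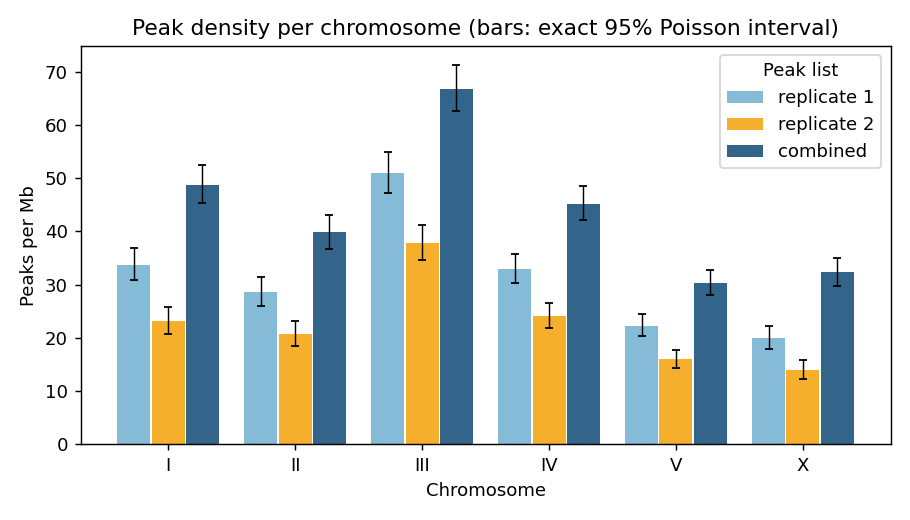
Peaks per Mb (y axis) on each chromosome (x axis) in the replicate 1, replicate 2 and combined lists, with exact 95% Poisson intervals. Chromosome III is highest in every list (50.9, 37.8 and 66.8 peaks per Mb).

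Along the autosomes, peaks were more frequent in the central 50% of the chromosome than in the outer parts. The centre held 2128 of 3686 autosomal peaks (57.7%, 56.1 to 59.3%), above the 95% range of 44.95 to 54.94% given by circular shifts (permutation p = 0.0003). The share was 56.8% in replicate 1 (permutation p = 0.004) and 54.9% in replicate 2 (permutation p = 0.0205). It was smaller among combined peaks in both replicates, at 54.7% (permutation p = 0.0287), against an upper limit of 54.2% from shifts. Among the stronger 50% of the combined list it was 54.8% (permutation p = 0.0315), against an upper limit of 54.2%. On X the centre held 268 of 570 peaks (47.0%, 42.9 to 51.2%; permutation p = 0.378). The difference between autosomes and X was 10.7 percentage points (permutation p = 0.0004 by circular shifts). Taken singly, the autosomes had between 55.5% (III) and 59.5% (V) of their peaks in the centre, and none passed after adjustment over 6 chromosomes (smallest adjusted p = 0.229, chromosome IV, permutation test).

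The densest 1 Mb bins were on chromosome III, where the bin from 12000001 to 13000000 came first and that from 4000001 to 5000000, with 95 peaks, came next. The sparsest lay on the right part of V, with 5 peaks between 17000001 and 18000000. The longest stretch without a combined peak was also there, from 16966000 to 17857730 (892 kb). By comparison, the longest such stretches were 382 kb on II, 359 kb on X, 216 kb on III, 201 kb on IV and 185 kb on I.

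**Figure D4:**
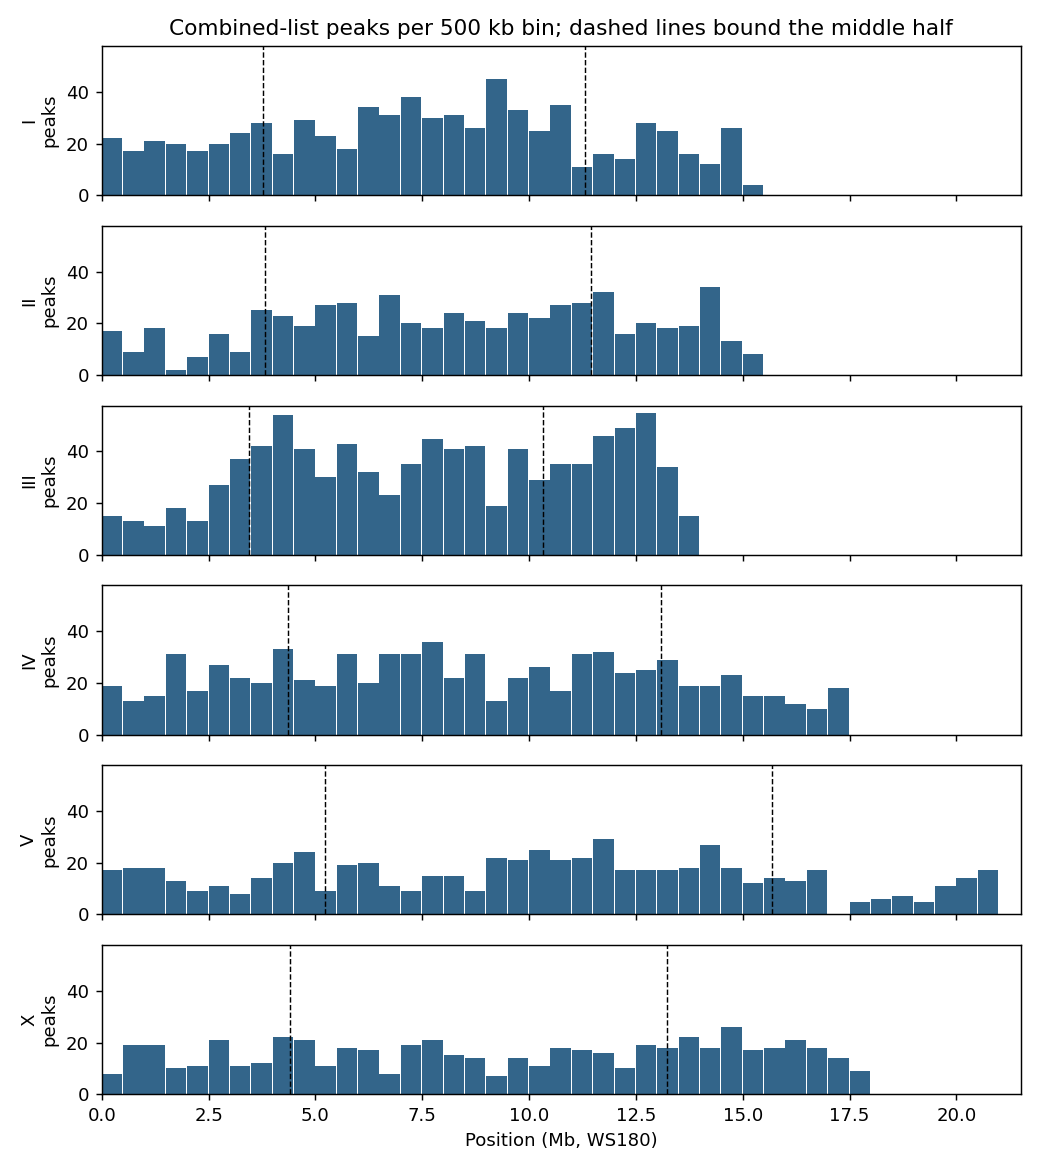
Combined-list peaks per 500 kb bin (y axis) along each chromosome (x axis, Mb on WS180), with dashed lines at the limits of the central 50% and a partial last bin on each chromosome. Bins are highest on chromosome III, and the right part of V holds the longest stretch without a peak (892 kb).

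Peaks also lay close together more often than random placement gave. Some broad regions were called as several peaks in a replicate list, so close peaks need not be separate sites. Of 4250 gaps between neighbouring combined peaks, 704 (16.6%) were 2000 bp or shorter. When each peak was placed at random within its own 200 kb bin, the mean was 8.67% and the highest of 1000 placements was 9.92% (permutation p = 0.001, the smallest that 1000 placements can give). After peaks up to 1000 bp apart were joined, 24.5% of the remaining gaps were 5000 bp or shorter, against 17.97% on average and 19.8% at most (permutation p = 0.001).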

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

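The 12 results of the replicate, combined-list and chromosome comparisons were recomputed under 53 alternatives in all, of which 49 kept the direction and the side of the threshold. The other 4 are shares without a test, which moved outside their main intervals. The size of an effect was not judged for the 49, and a chi-square statistic has no direction. The density ratio of X to autosomes, for example, fell below its main interval (0.661 to 0.790) in either replicate and in the stronger 50% of combined peaks (0.544). With a reciprocal overlap of 50% required, 44.3% of combined peaks overlapped both replicates and 29.6% neither. Among the stronger 50% of the combined list the shares were 87.7% and 0.517%, and the construction shows the cause, since weak peaks are left out. Agreement of the replicates was lowest when peak centres had to lie within 100 bp, at 58.8% of replicate 1 and 81.6% of replicate 2. With either replicate's list used alone in place of the combined one, the density ratio of X to autosomes was 0.592 to 0.613 and the autosomal share in the central 50% was 54.9 to 56.8%. Alternatives added after seeing the data were shifts of 20 to 100 kb, a common q threshold, the shortened replicate 1 list, bins of 1 Mb, spans as lengths, autosomes without chromosome III (X ratio 0.802) and peaks under 2000 bp. The tests of promoters, the CCAAT motif and gene lists, with their other settings, were not run, because no sequence or annotation of WS180 was used. No paired analysis was possible because the input samples, which share replicate numbers with the ChIP samples, had no file here. Depth is unknown, so neither the longer list of replicate 1 nor its smaller q values can be set against its number of reads.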

Other observations

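Among the tests of explanations, those on q values that were weaker in the combined list and the comparison of X strength among peaks of both replicates were chosen after the result was seen. The others were written before. Of these, the tests on the bound of q values and on X strength met their written criteria, and the test on X width met its written criterion against. The tests on the bound and on X strength were set to undecided afterwards, for the reasons given below. The test on X width was kept as evidence against width alone, within the limit given below.

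At most matched sites the combined q value was close to what both replicates gave together. Over 2005 combined peaks matched one to one with a peak of each replicate, the combined −log10 q was 0.956 times the sum of the replicate values (median, interquartile range 0.855 to 1.06). It exceeded the better replicate at 98.7% of them. The right end of chromosome I, from 15063992 to 15067642, stood apart. It ranked 3 in replicate 1 (q = 1.21e-171) and 3 in replicate 2 (q = 1.40e-166) but 35 in the combined list, with a q value of 1.66e-116 that was weaker than both. The ribosomal RNA gene array of C. elegans lies at the right end of chromosome I. Whether this peak falls within it was not tested. The combined list also held 9 peaks narrower than the narrowest replicate peak (139 bp), down to 1 bp on chromosome IV at 9741109, and 8 of these overlapped neither replicate.

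The 1176 combined peaks absent from both replicates may be sites that fell just under each replicate's threshold, which the lists leave open. Their combined −log10 q should then stay below 9.87, which is the sum of the weakest −log10 q values called in the replicates (7.45) times the upper limit of the central 95% of the ratio at matched sites (1.32). It did for 99.1% of them, but this bound lies above the median of the whole combined list (9.52), so weak chance calls would pass it too. Cut-off edges of replicate peaks are argued against as the general source, since 4.85% lay within 500 bp of a replicate peak. The read depth of the combined call stays unknown, and no biological explanation was tested.

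In an unplanned comparison that treats peaks as independent, combined peaks absent from both replicates were more frequent on X than on autosomes. The shares were 219 of 570 (38.4%) against 957 of 3686 (25.96%), an odds ratio of 1.78 (1.48 to 2.14; Fisher's exact p = 1.78e-09). Whether a lower strength of X peaks lies behind this cannot be told apart from the excess itself. The odds ratio was 1.21 (0.908 to 1.62) within 20 classes of combined q value, but peaks absent from both replicates are by their nature weak. Among peaks in both replicates the median −log10 q was 18.6 on X and 20.2 on autosomes (permutation p = 0.167). That comparison leaves out most weak peaks, so it cannot decide the question. The greater width of X peaks, taken alone, is argued against as the source of the excess. Peaks absent from both replicates were narrower (median 405 bp) than those in both (524 bp). Within 20 classes of width the odds ratio was 2.28 (1.87 to 2.76), so the excess was not smaller among peaks of like width. However, width rose with strength across combined peaks (Spearman's rho 0.38), and X peaks were wider but weaker. Classes of width thus set weaker X peaks against stronger autosomal ones, and a part for width among peaks of like strength stays open. The series has 1 stage and 1 sex, so no biological explanation was tested.

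At 27 of the 2005 matched sites the combined q value was weaker than that of the better replicate, and at 3 of these it was weaker than both. A wider outline drawn in the combined list may account for most of them. The combined peak was 1.54 times as wide as the wider replicate peak (median), against 1.04 at the other matched sites (permutation p = 1e-05). A numerical lower limit on q values is argued against, since the strongest of the 27 reached 50.9% of the largest −log10 q in the list. At the right end of chromosome I the width ratio was 1.003, which argues against a wider outline there, and the cause of the weaker combined value at that peak stays open.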
